A study of Rattus norvegicus with 6 samples.

How the data were processed

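RNA sequencing was done on rat bone marrow mesenchymal stem cells, the adherent marrow cells that can form bone, after transfection with an siRNA against S100A16 (siS100A16) or a control siRNA (siNC) during osteogenic differentiation. Each group had 3 samples. An siRNA is a short double-stranded RNA that lowers the level of the transcript it matches. Per the labels' protocols, cells at passages 3 to 5 were used, total RNA was taken with a column kit, and libraries were made with a kit whose name refers to single cells.

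The authors deposited 1 table of FPKM values (reads divided by gene length and by the total of reads counted) for 30560 genes in 6 columns. Per the submitters' processing notes, HISAT2 2.1.0 and DESeq2 1.14.1 were used, without a stated role. The same notes name a mouse genome build, whereas all 30560 gene identifiers carry the Ensembl rat prefix and 0 carry the mouse prefix. The read counter, the annotation release and any filter are not given in the sources used here. Columns named as controls were assigned to siNC and columns named as the experimental arm to siS100A16, the only other group in the labels, by the number in the sample titles. Whether samples with separate numbers came from separate cultures or animals is not stated, so the p-values measure the spread between these samples, which may be technical.

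The table gives identifiers without gene names, and the reference table used here, with 47357 rat genes, pairs 0 of them with an Ensembl identifier. Therefore no gene could be named. The silenced gene could not be looked up as a check of the labels, Smad4 could not be reported, and the 21 gene lists fixed before the data were examined were not tested. The rule for named genes, also fixed then, took the 10 largest rises and 10 largest falls among called genes with a symbol, members of the lists, and the silenced gene. It therefore named no gene. Only 2 identifiers that rose and 2 that fell are given: those with the largest fold changes by the same ordering without the need for a symbol, among called genes whose groups did not overlap. They were chosen after the values were available.

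Sequencing depth was worked out from the FPKM values. For all 22692 genes with a value above 0, the ratios between samples were ratios of whole numbers of reads (relative tolerance 3e-12). A single whole total per library made the gene lengths whole, within 0.002 nt, for 98.4% of the genes with a mean FPKM of at least 1. The totals of reads counted to genes were 7560820, 7135826 and 8059327 for siNC replicates 1 to 3, and 6937001, 6384262 and 5387539 for siS100A16 replicates 1 to 3. The reads of single genes summed to between 99.6% and 99.7% of these totals, because a factor common to a gene's reads and length cannot be recovered. In a simulation with known reads for the same genes, 6 of 6 totals and the reads of 98.8% of the genes with a mean FPKM of at least 1 came out exactly. A gene at 0 is compatible with up to 3 reads of these totals. This limit covers counting error only, since amplified reads are not independent molecules.

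Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance prior that followed the mean level, on the 12336 genes with a mean FPKM of at least 1 over all 6 samples. Values were used as deposited, without rescaling. Both groups entered 1 fit with the group as the only term and 1 variance per gene for both groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 in the two-sided test are called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The fit was tested on simulated reads for the same genes, with the spread of each group set from the real libraries. Among 12342 simulated genes tested, 13.0% of 100 genes changed 2-fold and 68.0% of 100 genes changed 4-fold were called, 6 unchanged genes were called, and without any changed gene 0 were called, with 5.8% at an unadjusted p under 0.05. The simulation changed at most 200 genes, drew genes independently and gave genes of similar level a common spread. It held no shift in scaling and no trend with length. Its rates therefore need not hold for the real libraries, where far more genes were called. Library measures were compared with an exact two-sided permutation test, whose smallest p for 3 samples against 3 is 0.1.

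Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a minimum mean FPKM of 5, 3 rescalings (median of ratios, TPM, quantile), a variance prior without trend, estimated sample weights, the replicate number as a block, other thresholds, and each sample left out in turn. Added after the data were seen were limma voom on the worked-out reads, removal of each library's trend with gene length (lowess, span 0.3, which also centres each library), removal of the 100 most abundant genes, thinning to the smallest total, and median of ratios together with removal of the length trend. Samples with the same replicate number showed no shared pattern: their deviations from the group means correlated at -0.03, 0.05 and 0.04. Noise between samples could hide a weak pairing, so pairing is not excluded.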

Results

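The transcriptome was measured by RNA sequencing in rat bone marrow mesenchymal stem cells under osteogenic differentiation, in 3 samples given siRNA against S100A16 and 3 given control siRNA. S100A16 belongs to the S100 family of calcium-binding proteins, and the comparison addressed which genes change when it is silenced during bone cell differentiation. Libraries held between 7135826 and 8059327 reads counted to genes in siNC and between 5387539 and 6937001 in siS100A16 (n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). Genes are described below by level, length and direction, since the table gives identifiers without names. The silencing of S100A16 itself was not assessed.

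The 10 most abundant transcripts took a smaller share of the reads after S100A16 siRNA. The 10 genes with the highest mean FPKM over all samples held 23.0% ± 0.461 of the reads in siNC and 12.0% ± 0.661 in siS100A16 (SD, n = 3 each), which separated all 3 samples of one group from all 3 of the other (exact two-sided permutation p = 0.1). The next 90 genes held 16.6% ± 1.39 and 16.4% ± 0.74 (exact two-sided permutation p = 1). By this ranking the difference in the 100 most abundant together, 39.5% ± 1.23 against 28.4% ± 0.851, lay in the first 10. With genes ranked by reads within each library, the top 10 held 24.19%, 24.88% and 24.26% in siNC and 14.28%, 13.68% and 14.90% in siS100A16. The top 100 then held 43.59%, 44.00% and 41.18% against 30.61%, 29.77% and 30.95%, so part of the difference lay beyond the first 10. Of the 10 genes with the highest mean FPKM, 8 fell past the test and 0 rose (limma, adjusted p under 0.05). The median log2 fold change over the 10 was -1.10. The gene with the largest change fell by 2.40 on the log2 scale, a level 5.26-fold higher in siNC. With median-of-ratios scaling 9 of the 10 fell. Among the 100 most abundant genes, 39 rose and 23 fell with values as deposited, and 27 rose and 29 fell with median-of-ratios scaling.

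**Figure D1:**
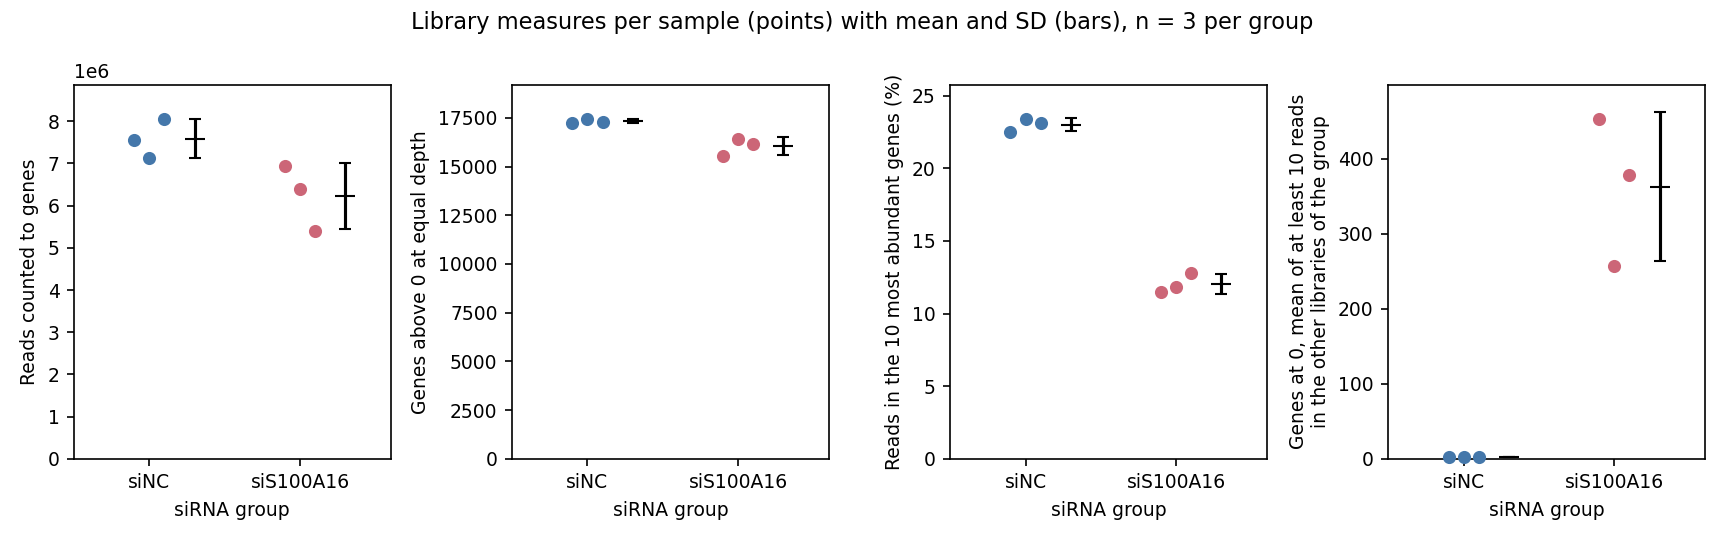
Each point is 1 sample; bars give the mean and SD of 3 samples per siRNA group, and every vertical axis starts at 0. From left to right: reads counted to genes, genes above 0 after thinning to 5387539 reads, percent of reads in the 10 most abundant genes, and genes at 0 in a sample although the other samples of its group had a mean of at least 10 reads; the last count is 2 in every siNC sample and between 257 and 453 in siS100A16.

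Across the transcriptome, 2556 of 12336 tested genes (20.7%) differed between siS100A16 and siNC, of which 2029 were higher and 527 lower after S100A16 siRNA (limma, Benjamini-Hochberg adjusted p under 0.05). The changes were mostly moderate. The median fold was 1.87 among genes that rose, and genes that fell had a median level 2.31-fold higher in siNC. A change of at least 2-fold was found for 1119 called genes, 770 higher and 349 lower, and one of at least 4-fold for 101, 37 higher and 64 lower. In 2555 of the 2556 called genes the 3 values of one group lay entirely on one side of those of the other. Such separation largely follows from being called with 3 samples against 3. Over all tested genes it held for 5129, or 41.6%, where chance gives 10% for a single gene. The genes share the same 6 samples and are not independent, and a common shift of unscaled values also separates groups. The excess over 10% is therefore no test against chance. 

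The balance between rises and falls depended on scaling. The median log2 fold change over all tested genes was 0.17 with values as deposited and -0.03 after median-of-ratios scaling. With the latter, 1742 genes were called, 894 higher and 848 lower, and quantile normalization gave 705 higher and 858 lower. Removing each library's trend with gene length, which also centres each library (median log2 fold change 0.01), gave 753 higher and 654 lower. The same step after median of ratios gave 663 and 655, but it centres the libraries either way and so does not separate length from centring. Median of ratios alone, without any length step, already gave a nearly even balance, so that balance cannot be put down to length. The genes higher under the deposited values, median of ratios, quantile normalization, TPM and length correction alike numbered 498, and those lower in all of them 405. These make up 24.5% of the rises and 76.9% of the falls first called. Each of these steps lowered the median log2 fold change from 0.17 (TPM to 0.15, quantile normalization to 0.03). Such a shift takes away rises and favours falls, so these shares do not compare how firm rises and falls are. With single samples left out, 473 of 2029 rises and 86 of 527 falls were called in every fit. No gene was called in opposite directions by the deposited values and any of the alternatives run.

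**Figure D2:**
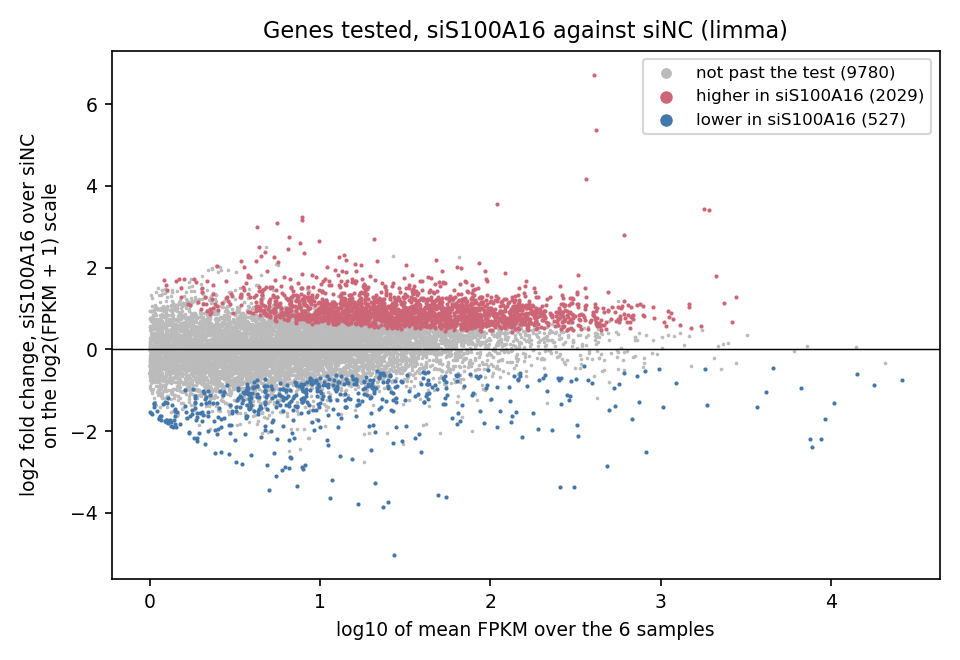
Each point is 1 of the 12336 tested genes; the horizontal axis is the log10 of mean FPKM over the 6 samples and the vertical axis the log2 fold change of siS100A16 over siNC on the log2(FPKM + 1) scale, values as deposited. The 2029 genes called higher lie mostly at intermediate levels, and the 527 called lower include 8 of the 10 most abundant genes.

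Called rises were most frequent among genes of intermediate to high level, where the test also has more power. In siS100A16 the squared coefficient of variation above sampling was 0.755 at 10 to 20 reads and 0.111 at 100 to 200 reads. The shares of calls below therefore depend on precision as well as on change. Of 768 genes with a mean FPKM from 100 to 1000, 408 (53.1%) were higher and 51 (6.6%) lower, with a median log2 fold change of 0.59. Of 2661 genes from 20 to 100, 928 (34.9%) were higher and 105 lower, and their median was 0.43. Of 4282 genes from 5 to 20, 580 (13.5%) were higher and 184 (4.3%) lower, with a median of 0.16. Of 4572 genes from 1 to 5, only 96 (2.1%) were higher and 171 (3.7%) lower, with a median of -0.02. In the 53 genes above 1000, 17 were higher and 16 lower, with a median of 0.10. After median-of-ratios scaling the medians of these 5 classes, in the order given, were 0.34, 0.19, -0.06, -0.19 and -0.15. The rescaling lowered all 5 medians by similar amounts, so that the changes of sign follow from this common shift. The calls under that scaling were 225 higher and 72 lower from 100 to 1000, 395 and 199 from 20 to 100, 224 and 327 from 5 to 20, 40 and 231 from 1 to 5, and 10 and 19 above 1000. Low genes also had many missing values after S100A16 siRNA: at equal depth, genes averaging 5 to 10 reads within a group were at 0 in 24.68% of siS100A16 values and 0.43% of siNC values. In simulated libraries without any change the median log2 fold change was -0.08 for genes from 1 to 5 FPKM and -0.01 for those from 100 to 1000.

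Fold changes also varied with gene length. The median log2 fold change was 0.44 in the 2471 shortest tested genes, up to 1232 nt, and -0.09 in the 2467 longest, from 3819 nt. The former held 580 rises and 128 falls, and the latter 84 rises and 145 falls. The counts by length shifted with scaling, which lowered the median of every class. The 518 genes under 200 nt had a median log2 fold change of -0.03 and 15 rises and 49 falls with values as deposited, and 13 and 51 with median of ratios. They were also low, with a median mean FPKM of 2.83, against 9.92 for genes from 200 to 1000 nt. Genes from 1 to 5 FPKM of any length had a like median of -0.02, so length and level are not told apart here. Genes from 200 to 1000 nt, with a median of 0.48, had 328 rises and 60 falls with values as deposited and 175 and 76 with median of ratios, and those from 1000 to 2000 nt had 936 and 108 against 425 and 170, so that rises stayed in excess in both classes. Genes from 2000 to 3000 nt had 500 rises and 103 falls with values as deposited and 200 and 178 with median of ratios, those from 3000 to 5000 nt had 225 and 122 against 74 and 218, and those above 5000 nt had 25 and 85 against 7 and 155. Called rises had a median length of 1680 nt and called falls one of 2368 nt, against 2258 nt for all tested genes. Across genes, which are not independent replicates, fold change and length correlated at a Spearman rho of -0.26.

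The largest rise was that of ENSRNOG00000030339, a gene of 67 nt, from 5.76 ± 3.59 to 802 ± 571 FPKM (SD, n = 3 each). It had 3, 1 and 5 reads in the siNC samples and 639, 100 and 288 in the siS100A16 samples, and its log2 fold change was 6.72 (SE 0.65, limma adjusted p = 0.00413). The second was ENSRNOG00000032997, of 69 nt, from 17.7 ± 12.5 to 814 ± 638 FPKM, with a log2 fold change of 5.37 (SE 0.72, limma adjusted p = 0.00487). Gene length divides the FPKM, so that for ENSRNOG00000030339 the single read of siNC replicate 2 was worth 2.09 FPKM.

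The largest fall was that of ENSRNOG00000055564, of 1395 nt, from 54.0 ± 24.9 to 0.722 ± 0.934 FPKM. Its reads numbered 339, 807 and 547 in siNC and 1, 16 and 2 in siS100A16, and the log2 fold change was -5.03 (SE 0.43, limma adjusted p = 0.00304). Over the alternatives this value ran from -4.69 (without siNC replicate 2) to -6.78 (limma voom on the worked-out reads). A pseudocount of 0.1 gave -6.60. The second was ENSRNOG00000057347, of 2368 nt, from 45.9 ± 35.9 to 1.21 ± 0.669 FPKM, with a log2 fold change of -3.86 (SE 0.81, limma adjusted p = 0.0157). Its siNC values were uneven, at 5.92, 75.5 and 56.3 FPKM, and without siNC replicate 2 or replicate 3 its adjusted p rose to 0.0647 or 0.0594, with log2 fold changes of -3.21 and -3.42. With limma voom on the worked-out reads it was 0.11, with a log2 fold change of -4.68.

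The siS100A16 samples differed among themselves more than the siNC samples did. Pearson correlations of log2(FPKM + 1) lay between 0.973 and 0.980 within siNC, between 0.901 and 0.925 within siS100A16, and between 0.881 and 0.948 across groups. The highest correlation across groups thus exceeded every correlation within siS100A16. The median SD of a gene was 0.17 in siNC and 0.37 in siS100A16 on the log2 scale, and 79.8% of genes had the larger SD in siS100A16. The first principal component carried 49.8% of the variance and placed the siNC samples at -34.2, -41.2 and -38.6 and siS100A16 replicates 1 to 3 at 60.6, 9.0 and 44.5. On this component siS100A16 replicate 2 lay between the siNC samples and the other siS100A16 samples. No sample was counted as a second deposit of another, as the chi-square per gene between samples of a group, with 1 degree of freedom, had a mean of 7.9 or more and a median of 1.34 or more. 

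Fewer genes were detected after S100A16 siRNA. Values above 0 were found for 17989 ± 81.2 genes in siNC and 16189 ± 416 in siS100A16 (SD, n = 3 each), and after thinning to equal depth for 17335 ± 105 and 16037 ± 462 (exact two-sided permutation p = 0.1 each). At equal depth, 2 genes in each siNC sample were at 0 although the other samples of the group had a mean of at least 10 reads. In siS100A16 replicates 1 to 3 there were 453, 257 and 378 such genes, where read sampling alone gives at most 0.011 per sample. For genes with 10 to 20 reads, the variance between samples was 1.81 times the mean in siNC and 11.59 times the mean in siS100A16. For genes with 100 to 200 reads it was 3.71 and 16.79 times the mean.

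**Figure D3:**
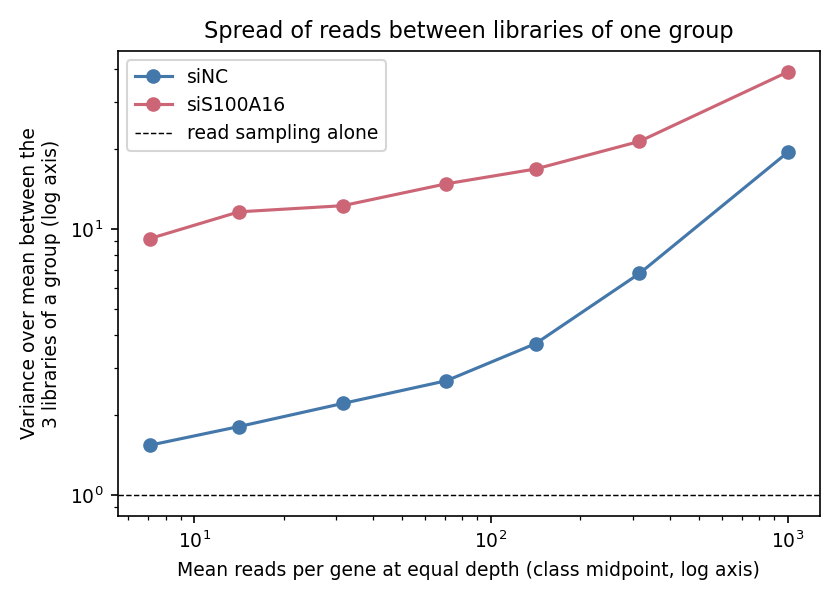
The variance over the mean of reads between the 3 samples of a group (log axis) against the mean reads per gene after thinning to equal depth (log axis), with 1 point per class of genes; the dashed line at 1 is read sampling alone. From 10 to 200 reads the siS100A16 curve goes from 11.59 to 16.79 and the siNC curve from 1.81 to 3.71.

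Leaving out single samples changed the number of calls. Without siNC replicate 1, 2 or 3 the calls were 1165, 570 and 1339, and without siS100A16 replicate 1, 2 or 3 they were 2439, 3209 and 2202. Genes called in the same direction with all 6 samples and in each of these 6 fits numbered 473 higher and 86 lower. The fit gives a gene 1 variance for both groups, while the median SD was 0.17 in siNC and 0.37 in siS100A16. Leaving out an siNC sample gives the wider group more weight in that variance, and leaving out an siS100A16 sample gives it less. These counts therefore do not show on which group's samples the calls rest.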

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

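Of the alternatives, those added after the data were seen are limma voom, the removal of the length trend (alone or with median of ratios), the removal of the 100 most abundant genes and thinning to equal depth. The 2556 calls became 1563 with quantile normalization, 1407 with the length trend removed, 1318 with median of ratios and the length trend removed, 1617 without the 100 most abundant genes and 1119 when a fold of at least 2 was also asked. The genes higher in siS100A16 (2029) became 894 with median of ratios, 705 with quantile normalization, 753 with the length trend removed, 663 with both median of ratios and length correction, and 863 without the 100 most abundant genes. The genes lower (527) became 848 with median of ratios and 858 with quantile normalization. Leaving out 1 sample gave between 570 (without siNC replicate 2) and 3209 calls (without siS100A16 replicate 2), with 477 to 2224 higher and 93 to 985 lower. Each such fit has fewer samples and weighs the unequal spreads of the groups differently. The cause of the other changes was not tested. The other settings stayed within 1.5 times the reported counts, with 2651 calls by limma voom and 2450 after thinning. With the replicate number as a block (replicate block) 2246 genes were called. The deviations of samples with the same number did not correlate above 0.1 in any pair, which does not exclude a weak pairing. For the 4 identifiers named, 77 of 80 alternative values kept their direction and stayed past the threshold, 3 kept the direction but not the threshold, all for ENSRNOG00000057347 with log2 fold changes of -3.21, -3.42 and -4.68 against -3.86, and 0 reversed. The planned tests of S100A16, Smad4 and the gene lists were not run, since identifiers could not be paired with names. At equal depth, genes averaging 10 to 20 reads were at 0 in 10.45% of siS100A16 values and 0.00% of siNC values.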

Other observations

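Thinning, the removal of the 100 most abundant genes and the removal of the length trend were added after the data were seen. The tests of spread against level, of detected genes at equal depth and of the direction of the length trend in single libraries were also chosen after their result was seen, and the counts of short and of absent genes had no prediction. Among 518 tested genes under 200 nt, 15 were higher and 49 lower in siS100A16 (limma, adjusted p under 0.05), although both of the largest rises named above belong to this class, and 12 and 30 of them were called under all the normalizations compared. These genes were also low (median mean FPKM 2.83), and their length and level were not told apart. Absence was also uneven: 29 genes had no read in any siS100A16 sample and at least 5 reads in every siNC sample. The reverse direction held 1 gene, and none of the 29 exceeded 32 reads in a sample. Genes averaging 5 to 10 reads within a group at equal depth were at 0 in 24.68% of siS100A16 values and 0.43% of siNC values. How many genes these rates alone put at 0 in all 3 samples was not worked out. No conclusion on lost expression is therefore drawn from the 29 genes.

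The wide spread and the missing genes in siS100A16 were not removed by equal depth. After thinning, the lowest siNC sample still had 843 more genes above 0 than the highest siS100A16 sample, which argues against read depth as the cause. If the 3 siS100A16 samples differed in level by a constant coefficient of variation, the excess variance over the mean would grow with the mean, but from 10 to 20 reads to 100 to 200 reads it grew only 1.49 times in siS100A16 (3.35 times in siNC), which argues against that as the whole cause in this range. Outside it the siS100A16 variance over the mean was 9.19 at 5 to 10 reads, 21.31 at 200 to 500 and 38.86 at 500 to 2000, so it was not flat among deeper genes. A nearly flat excess in low genes is what few RNA molecules, each copied into many reads, would give, and a low amount of RNA entering the siS100A16 libraries is a candidate explanation for those genes. The amount of RNA was not measured, and an effect of the siRNA on the cells stays open beside it.

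The excess of rises over falls (79.4% of calls higher) was not removed by thinning to equal depth, which left 80.1% higher. FPKM is already divided by each library's total, so thinning leaves the expected values unchanged. That result was therefore nearly fixed in advance, and no conclusion on depth is drawn from it. Without the 100 most abundant genes in totals and test, 53.4% of calls were higher, but that step rescales all other genes by the share difference already observed, and other rescalings gave a like balance (51.3% with median of ratios, 45.1% with quantile normalization). Whether a few abundant genes diluted the others in siNC therefore cannot be told apart from a wider rise of other genes, because FPKM is a relative measure. A biological change in the siS100A16 cells stays open and was not tested.

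The fall of fold change with gene length was also present within 5 equal classes of mean FPKM, at a rank correlation of -0.14, -0.12, -0.18, -0.30 and -0.27 from the lowest to the highest class (median -0.18). It was weak in the lower classes, so abundance as a part of the cause stays open. Among genes with a mean of at least 200 reads it was -0.43, but a cut on reads keeps short genes only at high FPKM and long genes also at low FPKM, so this value does not tell whether the noise of low genes took part. The trends of single libraries against the mean of the 6 were below 0 in 3 of 3 siS100A16 libraries, at a rho of -0.22, -0.04 and -0.15, but deviations from a common mean largely restate the group difference, and replicate 2 showed almost none. RNA breakage or size selection that differed between groups thus cannot be told apart from an effect of the siRNA, since all libraries of a group share its treatment. With the trend removed 1407 genes were called, of which 736 higher and 449 lower were among the 2556 called before.

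The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split called 2556 genes, 1 of the 10 splits (the real one) gave as many, and the highest of the other splits called 1. Every other split mixes samples of both groups, so the group difference adds to its spread and few calls follow. These counts therefore do not show what chance alone would give.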
